A study of Mus musculus with 6 samples.

How the data were processed

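RNA of the left lung lobe from 6 mouse embryos (strain C57/BL6, E18.5) was profiled, 3 wild type and 3 with a Smad1 knockout restricted to the lung epithelium. Per the labels' protocols, total RNA was purified with a Qiagen RNeasy kit and hybridised as biotin-labelled cRNA, with 1 array per animal. The deposited values are probe set intensity on a linear scale, as their range shows, and the submitters' processing notes name RMA (background correction, normalization and summary of probes). The software, its version and its settings are not given in the sources used here. Quartiles still differed between the deposited columns: the upper quartile ran from 170.3 in Smad1 CKO 3 to 283.8 in wild type 2. No scanner values were used here, so the background correction and normalization could not be repeated from the probes.

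Intensities were turned into log2(value + 1). The pseudocount makes differences of dim probe sets slightly smaller. The 64 control probe sets were left out of the tests. Of the 45037 others, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none there. Probe sets with several symbols were tested but not named. Of those with 1 symbol, 34741 were matched to a current gene table by gene identifier, and 0 symbols changed. Each of the 18193 genes was represented by its probe set with the highest mean over all 6 arrays. Among the genes named, the probe sets of Smad1, Lpcat1, Zfp385b, Apcdd1, Ddc, Piezo2, Fdps, Tpx2, Bub1, Tgm2, Ror1, Notch4, Sox9, Myocd, Slc4a1 and Eif2s3y did not all differ in the same direction. The same held for Sftpc and Napsa. The smallest root mean square distance between any 2 arrays was 0.2266 on the log2 scale, so no array was a copy of another.

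Genotype was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, default prior) with the pair as a fixed block, and Benjamini-Hochberg adjustment over the 45037 probe sets at 0.05. The pairs come from the design text, which describes paired mice, and from array names that share a letter and have neighbouring numbers. As a check, the deviations of arrays from their group means correlated within pairs, across probe sets, at 0.258, 0.604 and 0.598, and at 0.215 or lower between arrays of different pairs. Smad1 and Wif1 were fixed in advance and also adjusted over these 2 genes. Wif1 was taken from the title of the series, so its choice may not be independent of these arrays, which the adjustment over 2 genes does not allow for. Standard errors come from the fit, and SDs are over the 3 pair differences. Exact permutation of 3 arrays against 3 cannot reach 0.05, so none was used. Its smallest two-sided p is 0.1 if the pairs are ignored and 0.25 if arrays are exchanged only within pairs.

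Gene lists for pathways, lung cell types, other cell types and metabolic or stress programmes, 40 in all, were fixed before the data were examined, as were the tests, most alternatives and the rule for named genes. Lists were tested with camera (limma) with a preset correlation of 0.01 between genes, two-sided, adjusted over the lists. Each list was tested again with its correlation estimated and with fry, which asks whether the genes of a list move 1 way, or in its mixed form either way, without comparing them with other genes. With an estimated correlation no list was called, and fry called none for movement 1 way (lowest adjusted p = 0.321). The mixed form of fry called secreted Wnt antagonists (adjusted p = 0.0152) and ion and water transport (adjusted p = 0.0322). Camera with an estimated correlation rests on the residual degrees of freedom, 2 with 3 pairs and 1 with 2 pairs, so it could hardly call any list. Mesothelial markers, with an estimated correlation of -0.0677, below the preset value, still had an unadjusted p of 0.112 in it. A missing call in that test therefore decides little. Members were also adjusted over the list alone. A list's median was set against 2000 random lists of the same size drawn from genes of similar brightness. Their genes were drawn independently, so random lists lack the correlation within a real list, and the percentiles do not measure the spread between animals. Some genes belong to more than 1 list.

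By rule the text names Smad1 and Wif1, then up to 12 genes higher and 12 lower past the threshold in the same direction in all 3 pairs. Where fewer passed, places were filled by the smallest unadjusted p among genes with the same direction in all 3 pairs and at least a 1.5-fold difference, said not to have passed. From each list up to 4 members with the smallest p could be named. Sex-linked genes served as a check, and clone or predicted gene names were not printed.

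The fit was tested on 5 simulated data sets of 45037 probe sets with 200 planted changes in each, of 1 or 3 (log2) in equal numbers and in both directions, and a planted shift of the alveolar type 2 list. With 3 pairs it gave 19 false calls among 460, called 0% of changes of 1 and 88.2% of changes of 3 (log2), and recovered a planted list in 5 of 5 sets. With 2 pairs it called 19.6% and 100%, with 150 false calls among 772. The noise was drawn independently for each probe set, with a variance from the fitted prior that was the same on all arrays, so the outlying array was not simulated.

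The alternatives fixed in advance were a fit without the pair, the pair as a random block, an intensity trend in the variance prior, the dimmest probe sets left out (30025 kept), a further quantile normalization, each pair left out in turn, and the mean of a gene's probe sets. After the data were seen, 3 wild type against 2 CKO arrays without a pair term, cyclic loess normalization, no pseudocount, and an estimated correlation with 2 pairs were added, because of the control signals of Smad1 CKO 3. Cyclic loess and quantile normalization assume that most genes of each brightness do not differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.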

Results

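Gene expression was compared between wild type mouse lungs and lungs in which Smad1 had been removed from the epithelium by conditional knockout (CKO). Smad1 is a transcription factor that carries signals of bone morphogenetic proteins (BMPs), and the labels name Wif1, a secreted inhibitor of Wnt signalling, as its target. RNA of the left lung lobe was taken at E18.5, shortly before birth, from 3 pairs of mice, each with 1 wild type and 1 CKO animal. Each lobe was read on 1 Affymetrix Mouse430_2 array, which gave a deposited intensity for 45037 probe sets after control probe sets were left out. Median intensity per array ran from 69.96 to 77.8. The number of arrays, 3 per genotype, limits the precision, and the p-values of single genes measure only the spread between these samples. Those of gene lists (camera) compare the genes of a list with other genes, treated as nearly independent, and do not measure the spread between animals. The correlation estimated among alveolar type 2 markers, for example, was 0.612, against the preset 0.01. Differences are log2 CKO minus wild type, as the mean of the 3 pairs, with the SD over pairs.

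Smad1 CKO 3 stood apart from the other 5 arrays in its control probe sets. Its signal for 18S ribosomal RNA was 2887, against 242.5 to 297.2 on the others. Its beta-actin signal was 5820, against 18450 to 20900, and its Gapdh signal was 2501, against 6849 to 8748. Among the brightest 15012 probe sets, the median log2 difference was -0.30 in pair 1, -0.02 in pair 2 and -0.96 in pair 3, the pair that holds this array. Among the dimmest 15013 the medians were 0.14, 0.02 and 0.28. Medians without pair 3 are therefore given for the gene lists called with all 3 pairs and for those whose median then turned its sign. With Smad1 CKO 3 left out, Smad1 CKO 1 was the next most distant array. Across probe sets it correlated with the other 4 arrays at 0.9585 to 0.9705, while the highest value among these 5 arrays was 0.9943. Smad1 CKO 1 also differed from the others in sex-linked genes: its log2 level of Xist was 10.9, against 6.07 to 7.70 on the other arrays, and its level of the Y-linked Eif2s3y was 3.78, against 7.06 to 9.04. Pair 1 thus holds a difference of the kind seen between sexes together with the difference in genotype, and its values contain both.

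**Figure D1:**
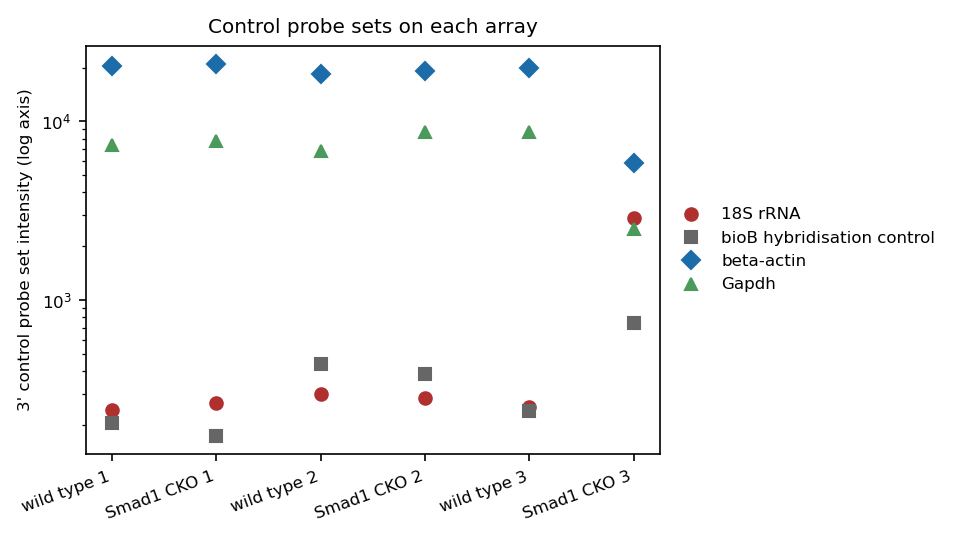
Intensity of the 3' control probe sets for 18S ribosomal RNA, the hybridisation control bioB, beta-actin and Gapdh on a log axis, with 1 point per array and control. On Smad1 CKO 3 the 18S signal was 2887 and the beta-actin signal 5820, while the other 5 arrays gave 18S signals of 242.5 to 297.2.

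The first question was whether the targeted gene itself differed. Smad1 mRNA was at 10.00, 10.09 and 9.53 (log2) in wild type lungs 1 to 3 and at 10.12, 10.62 and 9.05 in CKO lungs 1 to 3. The difference was 0.06 ± 0.51 (SD, 3 pairs), with a 95% interval of -0.56 to 0.67 (adjusted p = 0.831 over the 2 genes fixed in advance, Smad1 and Wif1). Its other probe sets gave differences of -0.28 and -0.18. After cyclic loess normalization between arrays the difference was 0.58, with an adjusted p of 0.00919, and after a further quantile normalization it was 0.49, with an adjusted p of 0.0211. The deleted part of Smad1 is not given in the sources used here, and a probe set outside it would not check the labels. The lobe also holds cells outside the epithelium, in which the gene was not targeted.

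Wif1 fell in the CKO lungs. Its difference was -1.52 ± 0.20 (SD, 3 pairs), a 2.87-fold lower intensity, with pair values of -1.55, -1.70 and -1.31 (adjusted p = 0.000506 over the 2 fixed genes). Mean intensity was 130.4 in wild type and 43.0 in CKO lungs, so the CKO level lay below the array median. No detection calls or background measure were used here, so this fold is one of intensities and at most a lower bound on that of the RNA. Across all probe sets Wif1 did not pass (adjusted p = 0.367). That value matters here, since Wif1 was chosen from the title, which may rest on these same arrays. With 3 wild type arrays against 2 CKO arrays, unpaired and without Smad1 CKO 3, the difference was -1.25 and the adjusted p over the fixed genes was 0.0714.

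The second question was which other genes differed with the loss of epithelial Smad1. The gene that passed across all probe sets was Sftpa1, which encodes surfactant protein A, a secreted protein of alveolar type 2 cells and airway cells. The dimmer of its 2 probe sets fell by 5.55 (SE 0.228), a 46.7-fold lower intensity, with -5.72, -5.07 and -5.85 in the 3 pairs (limma, adjusted p = 0.0205). That call was lost in the fit without the pair, after a further quantile normalization, without pair 1, and with 3 wild type against 2 CKO arrays. The CKO levels of this probe set were 5.49, 6.89 and 5.35 (log2), below the array median in CKO lungs 1 and 3 and above it in CKO lung 2. The folds of pairs 1 and 3, too, are therefore at most lower bounds. The brighter probe set, which represents the gene elsewhere in the text, gave -5.17 and did not pass (adjusted p = 0.102). This was 1 probe set lower and 0 higher past the adjusted threshold, while 5712 had an unadjusted p under 0.05. With a 1.5-fold limit as well, 1561 probe sets were higher and 3344 lower. Of these, 31.8% were higher, against 46% after cyclic loess normalization. At a planted log2 change of 3, simulated data with 3 pairs gave calls for 88.2% of probe sets, and at a change of 1 for 0%. The simulated noise was independent between probe sets and had no outlying array, so these shares are not those to be reached in the real data. There, genes with a mean fall beyond 3, such as Scd1, Hc and Aqp5 (below), did not pass.

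Several further genes lay far lower in all 3 CKO lungs without passing across all probe sets. Among them were Scd1, a desaturase that makes monounsaturated fatty acids, at -3.86 ± 0.67 (14.5-fold lower), and Hc, complement component 5, at -3.40 ± 0.53 (10.5-fold). Aqp5, a water channel of alveolar type 1 cells and glands, was at -3.05 ± 0.17 (8.29-fold, adjusted p = 0.0731). Pon1, a paraoxonase, was at -2.91, Bex2 at -2.90, the protease inhibitor Spink5 at -2.71 and the gap junction gene Gjb6 at -2.63. Zfp385b was at -2.39 and Lpcat1, which remodels surfactant phosphatidylcholine, was at -2.28. The 3 bright probe sets of Lpcat1 lay between -3.02 and -2.28, while its other 2 gave 0.57 and 0.31. The calcium-binding S100g was at -1.97 and Cyp4v3 at -1.91. Without pair 3, 24 probe sets were lower and 4 higher past the adjusted threshold, in a fit with fewer arrays that made 150 false calls among 772 on simulated data. Those lower included Sftpa1, Scd1, Hc, Pon1, Aqp5, Spink5, Gjb6, Bex2, Zfp385b, Lpcat1 and S100g.

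None of the genes with higher values passed across all probe sets (adjusted p = 0.367 for each of the 12 named). Gstm5, a glutathione transferase, was at 2.78 ± 1.39 (6.84-fold), with 3.42, 3.73 and 1.18 in the 3 pairs. Nmu, the neuropeptide neuromedin U, was at 1.78 ± 0.38 and Gng3, a G protein subunit, at 1.61 ± 0.91. The transcription factor Tbx19 was at 1.45, Rab3c at 1.33, the mast cell chymase Cma1 at 1.07 and Foxh1 at 1.03. Dnase1l2, Trpc7, Serpina3n, Entpd3 and Cdh3 (P-cadherin) lay between 0.77 and 0.99. Without pair 3, Gstm5 (3.57, adjusted p = 0.000639) and Nmu (1.99, adjusted p = 0.017) were called higher. The other 2 genes called higher there, the metallothionein Mt1 and the cadherin Cdh16, are named after their values were seen.

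**Figure D2:**
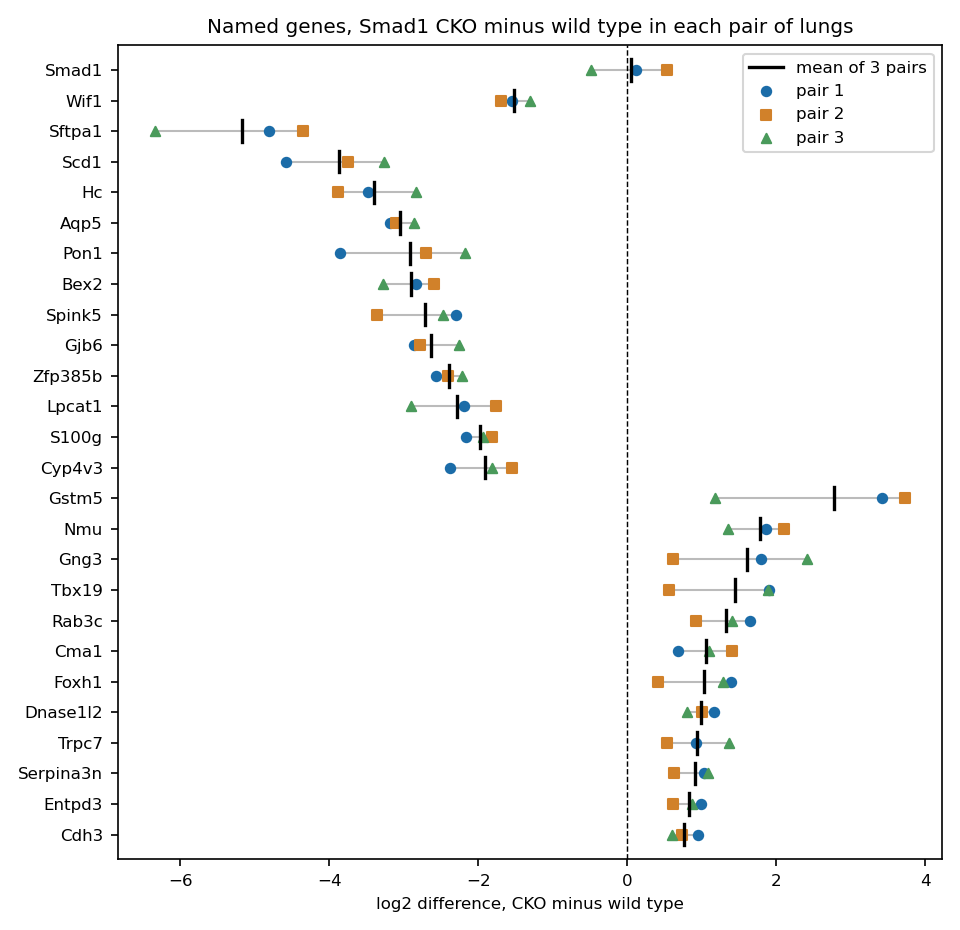
Log2 difference, CKO minus wild type, of Smad1, Wif1 and the 24 genes named by rule, with 1 point per pair and a black bar at the mean of the 3 pairs. Sftpa1 had the lowest mean, -5.17 for the probe set that represents it, and Gstm5 the highest, 2.78, while Smad1 had a mean of 0.06.

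Markers of both alveolar cell types fell. The 27 measured markers of alveolar type 2 cells, which make surfactant, had a median difference of -1.08 (camera, adjusted p = 4.77e-12, or 0.818 as the adjusted p with an estimated correlation), and 22 of them were lower in all 3 pairs. The test with an estimated correlation has 2 residual degrees of freedom and could hardly call any list, here or below. Adjusted over the list alone 15 members fell, none rose and 12 did not pass, while adjusted over all probe sets 0 passed by their representative probe set, in this list as in the other 39. Those with the smallest p were Hc, Sftpa1, S100g and Lpcat1, whose values are given above. The 25 markers of alveolar type 1 cells, the flat cells of the gas exchange surface, had a median of -0.80 (adjusted p = 8.17e-08, or 0.818 as the adjusted p with an estimated correlation), and 23 were lower in all 3 pairs. Over the list alone 5 of these fell and 20 did not pass. They included Aqp5, Rtkn2 at -1.45 ± 0.16, the sodium channel subunit Scnn1g at -1.10 ± 0.20 and the basement membrane collagen gene Col4a3 at -0.81 ± 0.23. Pair medians were -0.77, -0.53 and -2.00 for type 2 markers and -0.42, -0.34 and -1.47 for type 1 markers. Without pair 3 the medians were -0.66 (adjusted p = 6.56e-36) and -0.35 (adjusted p = 1.26e-09), and the members then ranged from -4.58 to 0.24 and from -3.15 to 0.37, so the fall was uneven within both lists. After cyclic loess normalization they were -0.46 (adjusted p = 6.8e-11) and -0.24 (adjusted p = 0.00023). Both 3-pair medians lay at percentile 0 among 2000 random lists matched for size and brightness. Those lists lack the correlation within the real ones (estimated at 0.612 and 0.542), so the percentiles share the limit of the camera p-values, here and below.

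General epithelial markers did not share this shift. The 27 members had medians of 0.05 and 0.22 in pairs 1 and 2 and -0.93 in pair 3, with -0.15 over all pairs (adjusted p = 0.589) and 0.14 without pair 3 (adjusted p = 0.0748). The list was higher after cyclic loess normalization, with a median of 0.34 (adjusted p = 0.018), and with 3 wild type against 2 CKO arrays, with 0.24 (adjusted p = 0.0056). With an estimated correlation its adjusted p was 0.933. Its 3-pair median lay at percentile 100 among brightness-matched lists. Prom1 at -0.76, Krt19 at -1.01, Ocln at -0.56 and Cldn4 at 0.50 had the smallest p, and none passed over the list alone. Transcription factors of the distal epithelium were not called (median -0.25, adjusted p = 0.155, and 0.0057 without pair 3, adjusted p = 0.934), with Cebpa at -0.95, Etv5 at -1.19, Sox9 at -0.75 and Sox11 at -0.77. The 3-pair median of this list lay at percentile 99.5 among brightness-matched lists.

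Genes of lipid synthesis fell as well. The 31 genes of fatty acid and phospholipid synthesis had a median of -0.55 (adjusted p = 7.34e-05, or 0.818 as the adjusted p with an estimated correlation). Over the list alone 3 fell, Scd1, Lpcat1 and Gpam, an acyltransferase of glycerolipid synthesis at -1.24 ± 0.62, while 28 did not pass. The 20 genes of cholesterol synthesis had a median of -0.56 (adjusted p = 0.00142, or 0.818 as the adjusted p with an estimated correlation), and 7 fell over the list alone. Insig1, a sterol-sensing regulator, was at -1.15 ± 0.40, and the enzymes Fdps, Cyp51 and Idi1 were at -0.98 ± 0.28, -1.01 ± 0.34 and -1.18 ± 0.52. Without pair 3 the medians were -0.29 (adjusted p = 4.16e-08) and -0.34 (adjusted p = 8.68e-05). After cyclic loess normalization they were -0.12 (adjusted p = 0.00257) and -0.31 (adjusted p = 0.00344). The 3-pair medians lay at percentiles 5.9 and 0.85 among lists matched for brightness.

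Genes of ion and water transport had a median of -0.22 over 20 members (adjusted p = 0.0403, or 0.818 as the adjusted p with an estimated correlation). Over the list alone 4 fell: Aqp5, the sodium channel subunits Scnn1g and Scnn1b (-0.85 ± 0.21) and the chloride channel Ano1 (-1.21 ± 0.70). Without pair 3 the list median was -0.021 (adjusted p = 0.00589). It was not called without pair 2 (median -0.46, adjusted p = 0.0624) or after cyclic loess normalization (median -0.10, adjusted p = 0.157). The call was also lost with an intensity trend (adjusted p = 0.0555) and after quantile normalization (median -0.055, adjusted p = 0.128). With 3 wild type against 2 CKO arrays the median was 0.011 (adjusted p = 0.161). The list kept its direction and call in 7 of 15 alternatives. The 3-pair median lay at percentile 80.8 among brightness-matched lists, above most of them.

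Endothelial markers fell, although Smad1 was targeted in the epithelium. The 37 members had a median of -0.89 (adjusted p = 2.46e-11), 33 were lower in all 3 pairs, and 24 fell over the list alone. With an estimated correlation the list was not called (adjusted p = 0.818). Car4, a carbonic anhydrase of lung capillaries, was at -1.43 ± 0.09, the receptor gene Tie1 at -0.92 ± 0.28, the transcription factor Erg at -1.16 ± 0.57 and Tmem100 at -1.20 ± 0.63. Pair medians were -0.61, -0.50 and -1.48, and the median without pair 3 was -0.59 (adjusted p = 1.48e-12). After cyclic loess normalization it was -0.37 (adjusted p = 2.69e-08). The 3-pair median lay at percentile 0 among brightness-matched lists. The 9 lymphatic markers were not called (median -0.29, adjusted p = 0.36), with Lyve1 at -0.84 and Pdpn at -0.78.

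Calls of fibroblast, matrix and pericyte genes depended on pair 3 or on the normalization. The 39 fibroblast and matrix genes had a median of -0.67 (adjusted p = 7.34e-05) and the 15 pericyte markers one of -0.59 (adjusted p = 0.0115), both with an adjusted p = 0.818 with an estimated correlation. Without pair 3 these medians were -0.13 (adjusted p = 0.0397) and -0.29 (adjusted p = 0.0677), and after cyclic loess normalization neither was called, at -0.032 and -0.11 (adjusted p = 0.315 and 0.262). The 3-pair medians lay at percentiles 0.2 and 5.65 among brightness-matched lists. No member passed over its list alone. Tgm2 was at -0.78, Tnc at -0.67, and the pericyte channel gene Trpc6 at -0.75 ± 0.05. Smooth muscle and myofibroblast markers were not called (median -0.34, adjusted p = 0.161), with Myocd at -0.88. Mesothelial markers, of the cells that cover the lung surface, had a median of -0.36 over 14 members (adjusted p = 0.0269, or 0.818 as the adjusted p with an estimated correlation) and -0.33 without pair 3 (adjusted p = 0.000739), while the call was lost without pair 2 at a median of -0.40 (adjusted p = 0.0966) and without the dimmest probe sets at -0.46 (adjusted p = 0.125), neither of them a smaller shift. After cyclic loess normalization the median was -0.27 (adjusted p = 0.0179), and the 3-pair median lay at percentile 15.1 among brightness-matched lists. Msln, mesothelin, fell over the list alone (-1.78 ± 0.38, 3.44-fold), and the other 13 did not pass.

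**Figure D3:**
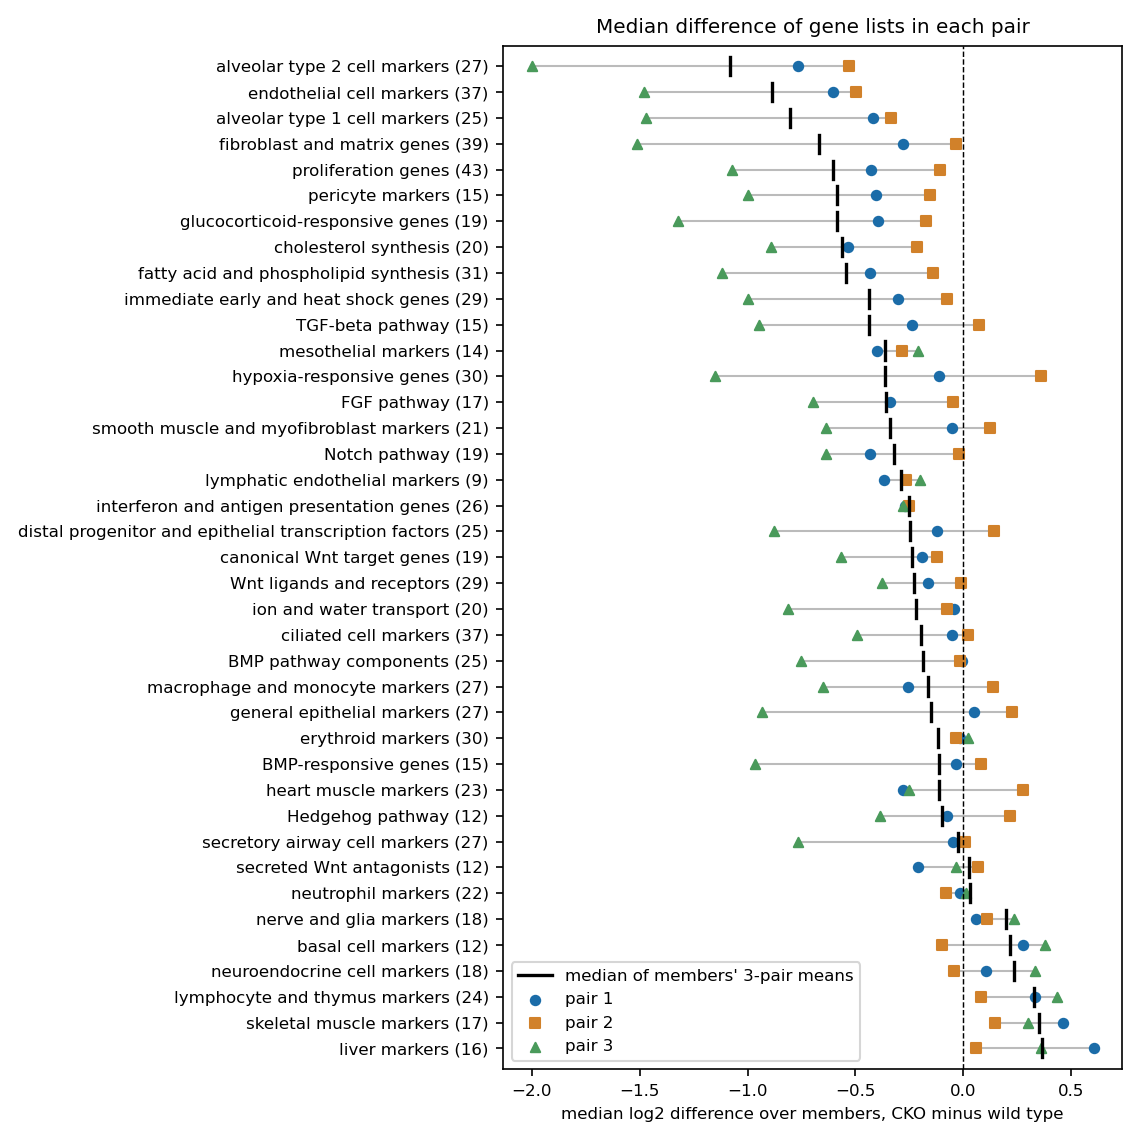
Median log2 difference, CKO minus wild type, over the members of 39 gene lists, with 1 point per pair, a black bar at the median over members of their 3-pair means, and the number of measured members in parentheses. Alveolar type 2 markers had the lowest bar, -1.08, with pair medians of -0.77, -0.53 and -2.00, and in most lists with a negative bar pair 3 lay lowest.

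The title names BMP and Wnt signalling, and the lists of both pathways were tested. BMP pathway components (25 genes, median -0.19, adjusted p = 0.36) and BMP-responsive genes (15 genes, median -0.11, adjusted p = 0.715) were not called. Without pair 3 their medians were -0.018 (adjusted p = 0.875) and 0.12 (adjusted p = 0.392), and after cyclic loess normalization 0.16 (adjusted p = 0.705) and 0.22 (adjusted p = 0.0954), so neither median had a settled direction. The 3-pair medians lay at percentiles 93.6 and 99.9 among brightness-matched lists. None of their members passed over the list alone, with Bmp6 at -0.57, Acvrl1 at -0.74, Sox17 at -1.12 and Id4 at 0.57. Wnt ligands and receptors were not called either (29 genes, median -0.23, adjusted p = 0.509), with Ror1 at -1.20 and Wnt2 at -0.72. Among 12 secreted Wnt antagonists, Wif1 and Notum, a Wnt-inactivating enzyme, fell over the list alone (adjusted p = 0.00304 and 0.0347), Notum by 0.84, and Dkk1 was at 0.45. The median of that list was 0.02, its mean -0.13, and its test leaned lower (adjusted p = 0.968). Without pair 3 its median was -0.05 (adjusted p = 0.405). Among 19 canonical Wnt target genes, Apcdd1 (-1.22 ± 0.38), Tnfrsf19 (-1.18 ± 0.52) and Notum fell over the list alone, and Axin2 was at -0.63 (adjusted p over the list alone 0.098). The whole list was not called (median -0.24, adjusted p = 0.36).

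In the FGF pathway (17 genes, median -0.36, adjusted p = 0.05, not called) Il17rd, a feedback inhibitor, and the receptor Fgfr2 fell over the list alone, at -0.89 ± 0.10 and -1.18 ± 0.52. Etv5 and Dusp6, which FGF signalling induces, were at -1.19 and -0.83 and did not pass. Notch genes were not called (median -0.32, adjusted p = 0.0973), with Notch4 at -1.14. Hedgehog genes were not called (adjusted p = 0.895), with a median of -0.10, a mean of -0.09 and a test that leaned higher, Gli1 being at 0.57 and Foxf1 at -0.86. Without pair 3 the Hedgehog median was 0.032 (adjusted p = 0.603), and after cyclic loess normalization the list was called higher (median 0.37, adjusted p = 0.0246). Its 3-pair median lay at percentile 99.9 among brightness-matched lists. TGF-beta pathway genes had a median of -0.44 (adjusted p = 0.0214, or 0.838 as the adjusted p with an estimated correlation), with Ccn2 at -0.94. Without pair 3 that median was -0.12 (adjusted p = 0.421), and after cyclic loess normalization it was 0.04 (adjusted p = 0.705). The 3-pair median lay at percentile 81.3 among brightness-matched lists.

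None of the airway cell lists was called. Secretory airway markers had a median of -0.02 (adjusted p = 0.861), or 0.05 without pair 3 (adjusted p = 0.994), while Pon1 and Retnla (-1.68 ± 0.66) fell over the list alone and Aldh1a1 was at -1.08. Ciliated cell markers had a median of -0.20 (adjusted p = 0.229), with Rsph4a at -0.74. Neuroendocrine markers had a median of 0.24 and a mean of -0.07 (adjusted p = 0.36). In that list Ddc, an enzyme of monoamine synthesis, and the mechanosensitive channel gene Piezo2 fell over the list alone, at -2.13 ± 0.56 and -1.38 ± 0.69. Basal cell markers had a median of 0.22 (adjusted p = 0.256), with Krt15 at -1.27 and Ngfr at 0.55. The 3-pair median of secretory markers lay at percentile 100 among brightness-matched lists. Those of ciliated, neuroendocrine and basal markers lay at 17.5, 87.2 and 83.2.

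Proliferation genes fell as a group, with a median of -0.60 over 43 members (adjusted p = 0.000119, or 0.818 as the adjusted p with an estimated correlation). No single member passed over the list alone. Tpx2, Anln, Bub1 and Melk, genes of mitosis and cell division, were at -0.90, -0.89, -1.11 and -0.73, with differences of -0.21, -0.11, -0.17 and -0.13 in pair 2. The mean of all Tpx2 probe sets was 0.20. Without pair 3 the list median was -0.30 (adjusted p = 0.000163), and after cyclic loess normalization it was -0.27 (adjusted p = 0.000123). The 3-pair median lay at percentile 0 among brightness-matched lists. Interferon and antigen presentation genes had a median of -0.25 over 26 members (adjusted p = 0.0381, or 0.818 as the adjusted p with an estimated correlation), with pair medians of -0.27, -0.25 and -0.28, and -0.25 without pair 3 (adjusted p = 0.000843). The call was lost without pair 1 (adjusted p = 0.274) and without pair 2 (adjusted p = 0.14), although the medians of -0.28 and -0.35 were no smaller, and it held in 6 of 15 alternatives. After cyclic loess normalization the median was -0.12 (adjusted p = 0.0272), and the 3-pair median lay at percentile 9.3 among brightness-matched lists. Oasl2, Usp18 and Ifit2, all induced by interferon, fell over the list alone, at -1.11 ± 0.26, -1.09 ± 0.33 and -0.93 ± 0.28.

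Glucocorticoid-responsive genes had a median of -0.58 (adjusted p = 0.000647) and immediate early and heat shock genes one of -0.44 (adjusted p = 0.0265), with adjusted p = 0.818 and 0.838 with an estimated correlation. Without pair 3 neither was called, at -0.21 (adjusted p = 0.0748) and -0.18 (adjusted p = 0.2), nor after cyclic loess normalization, at -0.056 and 0.031 (adjusted p = 0.264 and 0.587). The 3-pair medians lay at percentiles 14.6 and 27.3 among brightness-matched lists. Zbtb16 was at -0.92, Lcn2 at -1.46, Dusp1 at -0.82 and Jun at -1.14, and no member passed over its list alone. Hypoxia-responsive genes were not called (median -0.36, adjusted p = 0.313). Their median turned to 0.14 without pair 3 (adjusted p = 0.0727) and to 0.19 after cyclic loess normalization (adjusted p = 0.0954), and without pair 2 the list was called lower (median -0.71, adjusted p = 0.0205). Vegfa was at -0.58 (0.0089 after cyclic loess normalization).

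Of the blood cell lists, macrophage and monocyte markers were not called (median -0.16, adjusted p = 0.509), with Lyz2 at -1.45 and C1qa at -0.98. Neutrophil markers (median 0.03, mean -0.06, adjusted p = 0.627) and erythroid markers (median -0.12, test leaning higher, adjusted p = 0.939) were not called, with S100a9 at -0.86 and Slc4a1 at -0.78. Nerve and glia markers (median 0.20, adjusted p = 0.116) and heart muscle markers (median -0.11, test leaning higher, adjusted p = 0.509) were not called, with Gap43 at -0.75 and Nkx2-5 at 0.83. The 4 sex-linked genes were not called as a list (adjusted p = 0.402), but were called lower without pair 3 (adjusted p = 0.000739, or 0.911 as the adjusted p with an estimated correlation). Their median was -2.97 in pair 1 and 0.09 in pair 2, so this call rested on 1 pair. Lymphocyte and thymus markers (24 genes, median 0.33, adjusted p = 0.000163), skeletal muscle markers (17 genes, median 0.35, adjusted p = 0.000647) and liver markers (16 genes, median 0.36, adjusted p = 0.000647) rose as lists. With an estimated correlation none of the 3 was called (adjusted p = 0.818 for each). Without pair 3 their medians were 0.24, 0.29 and 0.35 (adjusted p = 0.00176, 0.00149 and 0.000739). Among brightness-matched lists the 3-pair medians lay at percentiles 92.4, 92 and 95.8. Their median wild type levels were 5.40, 5.23 and 5.31, in the dim range that was lifted in pairs 1 and 3, and after cyclic loess normalization none was called, at 0.22, 0.16 and 0.20 (adjusted p = 0.0954, 0.17 and 0.0954). Rag2 was at 0.56, Cd4 at 0.62, Cacng1 at 0.66, Ahsg at 0.65 and Alb at 0.51, and no member passed over its list alone.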

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

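Leaving out pair 3 and estimating the correlation of a list were planned, while their use to weigh explanations and the other tests in this part were chosen after the results were seen. The control probe sets for 18S ribosomal RNA, which no comparison used, drew attention on Smad1 CKO 3, where their signal lay far above the level in the wild type arrays. The 3' probe set read 2887, against 264 ± 29.0 (SD, 3 wild type arrays). The middle probe set read 2048, against 147 ± 31.6, and the 5' probe set 1648, against 118 ± 24.5. The other CKO arrays gave 267 and 283 for the 3' probe set. With 3 arrays per group, no test for a single outlying array was run.

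The control signals set Smad1 CKO 3 apart from the other 5 arrays. Weak hybridisation or scanning of the whole array cannot be decided here, since the deposited values were already normalized and do not give the absolute signal. The added bioB control was 1.69 times the highest of the other 5 arrays. That shows only that this control was not low relative to the rest of its array. A large share of ribosomal RNA in the labelled target cannot be told apart from other reasons, since the 18S signal, 9.71 times the highest of the other arrays, is what set the array apart and no separate measure was tested. Shorter cRNA or degraded RNA is consistent with a beta-actin 3' over 5' ratio of 1.56, against 1.209 to 1.394, and a Gapdh ratio of 1.007, against 0.8857 to 0.9359. All of these explanations stay open, no biological explanation was tested, and the array is the only one with this pattern among the 6.

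Alveolar type 2 markers were lower in the CKO lungs, and the poor array Smad1 CKO 3 as the whole cause is argued against, since the median was -0.664 in pairs 1 and 2 alone. Loss of signal among bright probe sets is argued against, since the median was -0.456 after cyclic loess normalization (adjusted p = 6.8e-11), although it was -1.08 before. A lower share of all epithelial cells is argued against in pairs 1 and 2, where general epithelial markers had a mean of 0.129 and a median of 0.138. Of these 27 markers, 15 were higher and 5 lower in both pairs. The mean of type 2 markers lay -1.12 from theirs (permutation p = 1e-05, the smallest that 99999 resamples can give, over genes, which are not independent replicates). That gap alone argues only against an equal fall, and members such as Sftpa1 and Hc (below) enlarge it. A lower share of type 2 cells as the whole cause would lower these markers alike, if no other cells made them. Such an equal fall is argued against. The SD over members in those pairs was 1.19, more than the size of the median and than the 0.22 expected from the spread between the pairs. Sftpa1 was at -4.58 and Hc at -3.68, but Sftpc at -0.38, Napsa at -0.02 and Sftpd at 0.05. Such uneven falls argue against a lower share as the whole cause only for markers that come from type 2 cells alone and lie below the array's ceiling. Lyz2 is also in the macrophage list, and Sftpc lay near the top of the range, at 14.46 (log2) in wild type 1. Napsa and Sftpd lay lower, at wild type means of 12.01 and 12.5, so a ceiling does not account for their values. Whether each marker comes from type 2 cells alone was not tested. Lower expression of some of these genes under the named loss of epithelial Smad1, with or without a smaller share of the cells, was not tested and stays open, and the list was not called with an estimated correlation.

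Endothelial markers were lower in the CKO lungs. The poor array Smad1 CKO 3 as the whole cause is argued against, since the median was -0.592 in pairs 1 and 2 alone. A lower share of all stromal cells is not excluded, since pericyte, matrix and smooth muscle genes also had a mean below 0 in those pairs, -0.153. Endothelial markers had a mean of -0.53, lying -0.378 from these genes (permutation p = 1e-05, the smallest possible, over genes). That argues only against an equal fall of all stromal genes. In those pairs 33 of 37 members were lower in both, and the SD over members was 0.29, less than the size of the median. A lower share of endothelial cells and lower expression in each would both give such falls, so they cannot be told apart here.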

How the results depend on the processing

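Counts moved with most settings, and genes such as Wif1 in CKO lungs lie in the dim range, where no measure of background was used here. The alternatives with 3 wild type and 2 CKO arrays, cyclic loess, no pseudocount, and an estimated correlation with 2 pairs were chosen after seeing the data, as was the use of the splits. Where no cause is named below, the cause was not tested.

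Probe sets past the adjusted threshold, 0 higher and 1 lower in the paired fit, were 0 and 0 without the replicate block, 0 and 6 with the pair as a random block, 2 and 30 with an intensity trend, 0 and 17 without the dimmest probe sets (30025 tested), 0 and 0 after quantile normalization, 1 and 0 with 3 wild type and 2 CKO arrays, and 0 and 2 after cyclic loess. Leaving out each pair gave 0 to 4 higher and 0 to 24 lower. At an unadjusted p under 0.05 and 1.5-fold, 1561 higher and 3344 lower in the paired fit became 287 and 1123 without the block, 2398 higher with the trend, 1745 lower after quantile normalization, 228 and 667 with 3 wild type and 2 CKO arrays, and 2016 lower after cyclic loess, where 2485 of the 4905 calls were shared with the same sign. Leaving out each pair gave 62 to 3615 higher and 593 to 7019 lower, the lowest without pair 1 and the highest without pair 2.

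The Smad1 difference of 0.06 was -0.18 without pair 2, -0.13 as the mean of its probe sets, 0.49 after quantile normalization and 0.58 after cyclic loess, and 0.03 and 0.32 without pairs 1 and 3. The Wif1 difference, -1.52, was -1.25 and no longer past the threshold with 3 wild type and 2 CKO arrays. Its adjusted p over the fixed genes was 5.62e-05 to 0.0714 over all alternatives.

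Lists called, 3 higher and 14 lower, were 0 and 0 with an estimated correlation, 0 and 0 with fry for movement 1 way, and 0 and 0 with an estimated correlation and 2 pairs. The lower count was 9 without the dimmest probe sets, 8 after quantile normalization, 7 with 3 wild type and 2 CKO arrays and 8 after cyclic loess. Alveolar type 2, alveolar type 1, endothelial, fatty acid, cholesterol and proliferation lists kept their direction and call in 12 of 15 alternatives each, all but these 3, although their medians, in this order, were smaller in size after cyclic loess (-0.46, -0.24, -0.37, -0.12, -0.31 and -0.27), with 3 wild type and 2 CKO arrays (-0.53, -0.33, -0.36, -0.14, -0.17 and -0.24), after quantile normalization (-0.59, -0.31, -0.46, -0.23, -0.43 and -0.41) and without pair 3. The TGF-beta test turned higher with 3 wild type and 2 CKO arrays (median -0.030) and after cyclic loess (0.043), and the general epithelial list turned higher in both (0.24 and 0.34). Without the block the interferon list was no longer called (adjusted p = 0.0546), and leaving out the block changed no other list call and not that of Wif1. Of single genes, Vegfa was at 0.0089 after cyclic loess and Tpx2 at 0.199 as the mean of its probe sets. Napsa and Sftpd, at -0.540 and -0.490 in the paired fit, were at 0.047 and 0.124 after quantile normalization, 0.0418 and 0.0876 with 3 wild type and 2 CKO arrays and 0.0891 and 0.164 after cyclic loess, and Napsa was at 0.0510 as the mean of its probe sets. Leaving out each pair gave -0.782 to 0.0504 for Sftpd, -0.282 to 0.663 for Aldh1a7, -0.116 to 0.839 for Cckar, -0.129 to 0.762 for Gsta4 and -0.148 to 1.26 for Mt1.

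With 4 of the 10 splits of the arrays parting all 3 pairs, a share under 0.05 cannot be reached. The real split gave 1 call, against at most 0 in the other 3, 4905 looser calls, against at most 1268, and 17 lists, against at most 18, so that 1, 1 and 2 of the 4 splits gave results as large. Splits that part 1 pair gave up to 4816 calls, which points to a structure of the samples, the distance of Smad1 CKO 3 from its partner.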

Other observations

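The values in this part were looked at after the results were seen. Without pair 3, some genes of the secretory airway list lay in the opposite direction to Pon1 and Retnla. Cckar, Gsta4 and Aldh1a7, named after their values were seen, rose over the list alone in the 2 remaining pairs, at 0.84, 0.76 and 0.66, with pair 3 values of -0.76, -0.99 and -1.18. Gsta4 is a glutathione transferase like Gstm5, and Aldh1a7 is an aldehyde dehydrogenase. Mt1, a metal-binding metallothionein, was at 1.11 and 1.40 in pairs 1 and 2 and at -1.41 in pair 3 in the probe set that represents it. Its dimmer probe set, the one called higher without pair 3, was at 2.08, 2.76 and 1.42, with a mean of 2.09 that did not pass with all 3 pairs (adjusted p = 0.367).

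The lower calls without pair 3 also held genes outside the lists of lung cell types. Crh, which encodes corticotropin-releasing hormone, was at -2.13, Tshb, a thyrotropin subunit gene, at -2.10, Dlk1 at -1.90 and Vnn1 at -1.73. These are named after their values were seen, and the fit with 2 pairs gave 150 false calls among 772 on simulated data.

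Pairs 1 and 2 had 512 probe sets lower and 90 higher by at least 1.5-fold in both, and all 3 pairs had 403 lower and 26 higher. The same sign in all 3 pairs was seen for 46.7% of probe sets, against 25% by chance for independent pairs. In pairs 1 and 2 it was seen for 59.1%, against 50% by chance. Across probe sets, which are not independent replicates, the differences of pairs 1 and 3 correlated at 0.584, those of pairs 1 and 2 at 0.334 and those of pairs 2 and 3 at 0.221. Pairs 1 and 3 also shared a shift with brightness. Among the brightest 15012 probe sets the median differences were -0.30, -0.02 and -0.96 in pairs 1 to 3. Among the dimmest 15013 they were 0.14, 0.02 and 0.28. Such a shift also gives like signs and correlation, so these values do not measure an effect of genotype alone.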
